A study of Homo sapiens with 10 samples.

How the data were processed

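RNA was measured by sequencing in 10 libraries of H441, an established human lung adenocarcinoma line grown with 10% fetal bovine serum. Per the labels, 3 libraries were wild type (WT), 3 came from cells in which TET1 had been knocked out from the wild-type line with CRISPR-Cas9 (KO), and 2 came from cells transfected with a plasmid carrying full-length human TET1 (OE). Another 2 libraries were labelled wild type without treatment but were titled Lipo, a word the labels do not explain. Total RNA (1 µg) was converted with a stranded total RNA kit for low input. The processing notes name HISAT2 2.1.0, FastQC, featureCounts, edgeR and the GRCh38 genome build, with no role or order, and whether counting took strand into account was not given in the sources used here. Values for antisense and overlapping transcripts therefore carry that uncertainty.

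The deposited table holds raw read counts per gene, as whole numbers without normalization or filtering. It had 62710 entries, of which 1 (ANK2) carried no values and was left out, and 28084 of the remaining 62709 had a count in any library. A further 2 columns matched none of the 10 samples and were not used here. Symbols were taken from the table, and 20930 identifiers had none. Positions and gene types came from GENCODE release 29, which held 58273 of the identifiers and 15352 of those tested. Y-linked genes and XIST are not named in the results, but 13 such genes stayed among those tested and counted.

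Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr on the 4 groups, which left 15832 genes. Libraries were scaled by TMM, and a robust quasi-likelihood model was fitted to all 10 libraries together, with 1 coefficient per group and 6 residual degrees of freedom. The comparisons were KO with WT, OE with Lipo, Lipo with WT, and the difference between the KO effect and the OE effect. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05, and adjusted p-values for genes below are from this edgeR test. Lipo was chosen as the control for OE because its title sets it apart from WT, and WT was tried in its place. Levels are CPM, read counts scaled to the TMM-adjusted library size, given as mean ± SD over the libraries of a group, and fold changes are those fitted by the model, with the standard error (SE) of the log2 fold change. The labels do not say whether replicates were separate cultures, so p-values speak of the spread between these libraries alone.

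A gene with no counts in a group was given a floor of 3 counts over the group, and its fold is printed as a bound. With 1 to 3 counts, the ratio of summed levels is printed with an exact 95% interval. Intervals and floors cover counting error only.

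Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, which made the call, with camera at a correlation estimated per list and fry beside it. P-values were adjusted over the 39 lists with at least 5 tested members. Of 42 lists written, Neuroendocrine genes (3 tested members), Fibroblast marker genes (2) and HOX genes (3) were too small to test. Members that rose or fell were counted at adjusted p under 0.05 over all genes, and again adjusted over the list alone. The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined.

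By that rule the text names TET1, TET2 and TET3, and the 10 genes with the largest rise and the 10 with the largest fall in KO and in OE. For Lipo with WT it names 5 of each. These had to pass the test, to reach a mean log2 CPM of 2, to show no overlap in CPM between the groups, and to have a symbol other than a clone name, with pseudogenes passed over. For each list described, up to 4 members with the smallest p are named. Genes outside the rule are said to be so where they appear.

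The alternatives were RLE scaling, library size alone, DESeq2 1.42.0 with its own filtering, no filter on low counts, and a stricter filter of 1 CPM in 3 libraries with a total of 100. Others were leaving out mitochondrial and structural RNA genes, protein-coding genes alone, only the groups compared, the replicate number as a block, WT or all 5 wild-type-labelled libraries as control, and each library left out in turn. Leaving out WT 1 and KO 1 together and the block in the fit of all 10 libraries were added after the data had been seen.

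Total counts per library ranged from 20994462 to 25981097. The test was also checked on simulated data with 200 changed genes in the same design. It recovered 71.6% of genes given a 2-fold change in a comparison of KO with WT, 61.2% in one of OE with Lipo and 56.7% in one of Lipo with WT. The corresponding shares were 19.4%, 11.9% and 14.9% at 1.5-fold and 92.4%, 86.4% and 98.5% at 4-fold. False calls were 2 of 124, 8 of 114 and 7 of 120 calls in the same order. The changed genes were drawn only from those above a minimum mean level, and the simulated libraries were independent, so these shares do not hold for all genes tested. Each simulated gene also had the same spread in every group. The shares and false calls therefore do not carry over to groups of unlike spread. Results for some genes are not reported here.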

Results

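Messenger and other long RNA was measured by total RNA sequencing in H441 lung adenocarcinoma cells whose TET1, per the labels, had been knocked out or added. TET1 is an enzyme that oxidises methylated cytosine in DNA. The libraries fell into 4 groups, of 3 wild-type (WT), 3 knockout (KO), 2 overexpression (OE) and 2 wild-type libraries titled Lipo. Total counts were 22563999, 25981097 and 22571663 for WT 1 to 3, and 21817106, 24820484 and 23141660 for KO 1 to 3. They were 24602887 and 22513656 for Lipo 2 and 3, and 20994462 and 22443266 for OE 1 and 2. Mitochondrially encoded genes took 5.71% ± 0.387 of counts in WT (SD, n = 3), 6.17% ± 0.954 in KO (n = 3), 8.38% ± 0.480 in Lipo (n = 2) and 4.81% ± 0.107 in OE (n = 2).

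TET1 itself (ENSG00000138336, chromosome 10, 68560656 to 68694482, plus strand, GRCh38) was barely transcribed in the unmodified line. WT 1, 2 and 3 held 2, 7 and 0 reads of TET1, and Lipo 2 and 3 held 0 and 1. A count of 0 allows up to 0.131 CPM in WT 3 and 0.125 CPM in Lipo 2. The pooled level was 0.125 CPM in WT (95% interval 0.0571 to 0.237) and 0.0218 CPM in Lipo (5.51e-04 to 0.121). In OE, TET1 stood at 882 and 957 CPM (919 ± 53.1, n = 2), and the OE to Lipo ratio was 42305 (95% interval 7592.5 to 1671000, adjusted p = 2.03e-10). KO 1, 2 and 3 held 4, 0 and 8 reads, or 0.168 CPM pooled (0.0869 to 0.294, with up to 0.117 CPM allowed in KO 2). The KO to WT difference was 0.42 on the log2 scale (SE 0.87, adjusted p = 0.813), and it was -0.55 without KO 3 and -0.11 without WT 3, while only 2 WT reads remain without WT 2. A loss of TET1 RNA in KO was therefore not detectable at this depth, and read counts do not report on a small edit in the gene. The related enzymes TET2 and TET3 did not pass the test in KO (log2 -0.04 and -0.13), in OE (0.32 and 0.18) or in Lipo (-0.25 and -0.52, with adjusted p = 0.524 and 0.119).

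To ask what the labelled knockout of TET1 changes, KO was compared with WT. CD74, the invariant chain that accompanies MHC class II molecules (ENSG00000019582, chromosome 5, 150401637 to 150412929), rose 5.10-fold, from 30.6 ± 3.86 to 156 ± 31.8 CPM (n = 3 each, log2 SE 0.15, adjusted p = 1.13e-07). CFI, a protease that inactivates complement, rose 4.93-fold from 6.48 ± 1.60 to 31.9 ± 3.16 CPM. The hyaluronan receptor CD44 (ENSG00000026508, chromosome 11, 35138870 to 35232402) fell from 12.6 ± 3.71 CPM in WT to 0.0872 ± 0.0866 CPM in KO, where its 3 libraries held 6 reads in all (141-fold lower, log2 SE 0.45, adjusted p = 9.07e-08). SLC6A14, an amino acid transporter, was 113-fold lower, at 0.153 ± 0.108 CPM in KO.

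Several genes transcribed in WT had no reads in any KO library. The metallothionein MT1E stood at 66.1 ± 27.5 CPM in WT and was at least 1555-fold lower in KO, with the caveat that reads can be shared between metallothionein paralogs. PRSS21, a membrane-bound serine protease, was at least 282-fold lower (11.8 ± 0.572 CPM in WT). IFNLR1, a receptor subunit for type III interferons, was at least 249-fold lower (10.5 ± 1.25 CPM), and the transcription factor NFE2L3 at least 85.4-fold lower (3.59 ± 0.270 CPM). TUSC3, a subunit of the oligosaccharyltransferase, had 1 read against 866 (WT to KO ratio 857, 95% interval 153 to 33886). ZC4H2 had 2 against 334 (165, 45.4 to 1370). GNAQ, a G protein alpha subunit, fell 73.4-fold from 54.0 ± 5.42 CPM, and TMCC3 fell 71.4-fold. As these folds rest on few KO reads, single libraries moved them. The log2 change went to -6.53 for CD44 without KO 2 and to -6.89 for GNAQ without KO 1. No reads of TUSC3 without KO 1 or of ZC4H2 without KO 2 are left in KO, and too few for a fold of CD44 without KO 3 or of TMCC3 without KO 1.

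The rises named by the same rule for KO also included PLEKHS1 (3.18-fold, to 145 ± 13.1 CPM), RAB29, a small GTPase (3.91-fold), and C16orf96 (log2 1.74). They held the pluripotency and squamous lineage factor SOX2 (3.24-fold, to 92.3 ± 17.7 CPM), the basement membrane protein FRAS1 (3.62-fold), the gelatinase MMP9 (log2 1.82, 115 ± 45.6 against 32.6 ± 21.6 CPM) and XAF1 (log2 2.51, 0.424 against 0.0727 CPM, near the limit of detection). With all 5 wild-type-labelled libraries as control, SOX2 (log2 1.00, adjusted p = 0.0801) and FRAS1 (0.73, adjusted p = 0.330) no longer passed, and RAB29 went to 1.38. MMP9 lost its call without Lipo 2 or Lipo 3, which entered through the shared error estimate (adjusted p = 0.0506 and 0.0502), or with no filter on low counts (0.128), and moved to 2.51 without WT 1. XAF1 lost its call without WT 2 (adjusted p = 0.0613) or KO 3 (0.0684), and too few WT reads for a fold are left without WT 3. In all, 1992 of 15832 genes passed the edgeR test, 812 higher and 1180 lower in KO, and 712 of them differed at least 2-fold (197 higher, 515 lower). The count was 1125 without WT 2, 1238 without WT 3 and 1216 when WT and KO alone were fitted. It thus depended on libraries outside the comparison, which share the error estimate.

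Lists of mesenchymal genes and of matrix proteases were called lower in KO. In the Mesenchymal and EMT list, 11 of 22 tested members fell and 2 rose (13 and 2 adjusted over the list alone), with 1 rising without Lipo 2 or Lipo 3. Beside CD44, the matrix glycoprotein fibronectin, FN1, fell 5.15-fold from 2179 ± 549 to 423 ± 74.1 CPM (adjusted p = 4.86e-07). Tenascin C, TNC, fell from 221 ± 68.4 to 70.0 ± 7.87 CPM, and NT5E, the ectoenzyme that makes adenosine, from 327 ± 60.5 to 125 ± 28.0 CPM. The list was called lower by camera (adjusted p = 3.88e-10, and adjusted p = 0.0157 with an estimated correlation, the only KO list that passed so). That estimated value rose to 0.0946, 0.0677 and 0.0531 without KO 1, KO 2 and KO 3. The mesenchymal list was called lower in Lipo against WT as well (camera, adjusted p = 5.6e-06), so its fall was not particular to KO. Both comparisons used the same WT libraries. Of 18 Matrix proteases and inhibitors, 6 fell and 1 rose (7 and 1 adjusted over the list alone), among them urokinase, PLAU (639 ± 95.1 to 268 ± 29.3 CPM), its receptor PLAUR (49.5 ± 2.37 to 25.9 ± 4.33 CPM) and cathepsin L, CTSL (50.5 ± 6.05 to 21.8 ± 0.549 CPM). The collagenase MMP1 fell from 96 reads to 5. The 1 rise was lost without Lipo 2 or Lipo 3, and 2 rose without KO 1. That list was called lower (adjusted p = 8.02e-04, and adjusted p = 0.144 with an estimated correlation).

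Of 21 YAP and TAZ targets, 7 fell (8, with 2 rising, adjusted over the list alone), such as ASAP1 (60.2 ± 3.03 to 19.8 ± 5.24 CPM) and MYOF (836 ± 36.6 to 457 ± 73.3 CPM). With all 5 wild-type-labelled libraries as control 4 fell and 2 rose, and 1 rose without KO 1, KO 3 or WT 1. The list was called lower (adjusted p = 7.10e-04, and adjusted p = 0.309 with an estimated correlation). Of 22 TGF-beta targets, 7 fell (7, with 2 rising, adjusted over the list alone), including the receptor TGFBR2 (96.2 ± 6.42 to 49.4 ± 6.26 CPM) and the corepressor TGIF1 (log2 -0.69). Their call (adjusted p = 0.0258, and adjusted p = 0.442 with an estimated correlation) ended without WT 1 (0.0610) or KO 1 (0.187) and with protein-coding genes alone (0.0745). In this list 1 rose without KO 1, KO 2 or WT 1, and 5 fell and 1 rose with all 5 wild-type-labelled libraries. Among 21 Genes often methylated in lung cancer, 5 fell and 2 rose, also when adjusted over the list alone. The death-associated kinase DAPK1 went from 7.11 ± 1.43 to 1.31 ± 0.511 CPM, the protease inhibitor TFPI2 from 132 ± 5.65 to 66.6 ± 9.97 CPM, and E-cadherin, CDH1, from 1151 ± 39.4 to 686 ± 73.7 CPM. That call (adjusted p = 0.0212, and adjusted p = 0.160 with an estimated correlation) ended without KO 1 (0.0715), and 1 rose without WT 2.

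A squamous and a gastrointestinal list were called lower with the preset correlation alone. In the Basal and squamous list, 6 of 12 members fell and 1, SOX2, rose (6 and 1 adjusted over the list alone). The cornified envelope proteins SPRR1B (44.9 ± 16.0 to 4.65 ± 1.62 CPM) and SPRR1A (log2 -2.16) and the keratin KRT6A (24.3 ± 10.1 to 8.47 ± 1.58 CPM) were among those that fell. The list was called lower (adjusted p = 0.0182, and adjusted p = 0.160 with an estimated correlation), but not without KO 1 (0.0618), and the rise of SOX2 did not pass with all 5 wild-type-labelled libraries as control. Of 8 Gastrointestinal lineage genes, 3 fell (4, with 1 rising, adjusted over the list alone), led by the adhesion molecule CEACAM6, which fell 5.35-fold from 496 ± 39.4 to 92.7 ± 19.2 CPM. Its list (adjusted p = 0.0212, and adjusted p = 0.194 with an estimated correlation) was not called without KO 2 (0.0530). CEACAM6 alone fell without KO 2 or WT 3, and 1 member fell with all 5 wild-type-labelled libraries as control, while 4 fell and 1 rose without WT 1.

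The lists called higher in KO were of ribosomal, respiratory chain and MHC class II genes. Each of these lists was also called higher in Lipo against WT, a comparison of wild-type libraries. A higher call against WT was therefore not particular to KO, but both comparisons used the same WT libraries. In Lipo these calls did not hold with an estimated correlation, and no single ribosomal or respiratory chain gene of these lists passed there. The lists were not tested with all 5 wild-type-labelled libraries as control. Of 38 Cytosolic ribosomal proteins, 26 rose and none fell (33 rose adjusted over the list alone), with a median log2 change of 0.57. RPL30 rose from 637 ± 5.99 to 1078 ± 145 CPM, RPL37 by 0.88, RPL23 by 0.73 and RPL5 by 0.66 on the log2 scale. The list was called (adjusted p = 2.28e-15, and adjusted p = 0.345 with an estimated correlation), and without KO 3 the count was 20 rising and 1 falling. In the class II list, 2 of 6 members rose, CD74 and the class II transactivator CIITA (0.720 ± 0.268 to 4.42 ± 0.125 CPM, log2 2.61, or 1.63 with all 5 wild-type-labelled libraries). It was called (adjusted p = 1.22e-04, and adjusted p = 0.0766 with an estimated correlation), with the same 2 of 6 adjusted over the list alone. Of 34 Oxidative phosphorylation subunits, 5 rose and 1 fell (7 and 1 adjusted over the list alone), including the ATP synthase subunit ATP5MC1 (26.5 ± 3.42 to 66.4 ± 18.2 CPM) and, downward, CYC1 (log2 -0.59). That call (adjusted p = 0.0225, and adjusted p = 0.598 with an estimated correlation) ended without KO 3 (0.211). The number that rose was 2 without WT 2, Lipo 2, Lipo 3, OE 1, OE 2 or KO 3, 1 without WT 3 and 8 without KO 2.

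Immune gene lists other than class II were not called by camera in KO, while fry called Nucleic acid sensing lower (adjusted p = 0.0265). Of 46 Interferon-stimulated genes, 6 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.276), with the antiviral proteins IFIT2 (4.77 ± 0.598 to 11.8 ± 0.902 CPM) and IFIT3 (3.16 ± 1.06 to 9.26 ± 0.595 CPM) higher and OAS1 (26.2 ± 4.85 to 14.3 ± 2.41 CPM) and GBP3 (39.9 ± 2.70 to 23.4 ± 3.89 CPM) lower. The class I list was not called either (adjusted p = 0.970). Among 19 Immune checkpoint and NK ligands, 3 rose and 3 fell (4 and 3 adjusted over the list alone, adjusted p = 0.674), with higher VTCN1 (log2 1.65), IDO1 (1.57), which breaks down tryptophan, and LGALS9 (8.44 ± 2.31 to 19.4 ± 4.15 CPM). Of 30 Chemokines and cytokines, 3 rose and 4 fell (4 and 5 adjusted over the list alone, adjusted p = 0.705). The chemokine CX3CL1 fell from 123 ± 13.1 to 27.3 ± 6.59 CPM, and IL18 rose from 15.5 ± 7.05 to 41.5 ± 11.9 CPM.

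Single genes of lung epithelial and hypoxia lists changed in KO without a call by camera, though fry called the alveolar (adjusted p = 0.0141) and the hypoxia list (0.0265) lower. Surfactant protein B, SFTPB, fell from 195 ± 20.4 to 49.5 ± 9.47 CPM and the phosphate transporter SLC34A2 from 1337 ± 280 to 474 ± 34.8 CPM, in an Alveolar type 2 and club cell list with 4 members falling and 2 rising of 22, also adjusted over the list alone (adjusted p = 0.307). Desmoplakin, DSP, fell from 362 ± 16.3 to 117 ± 15.5 CPM, in an epithelial junction list with 5 falling and 2 rising of 29 (6 and 3 adjusted over the list alone, adjusted p = 0.420). Among 32 Hypoxia and glycolysis genes, 8 fell and 2 rose (9 and 3 adjusted over the list alone, adjusted p = 0.0979), among them VEGFA (678 ± 99.0 to 371 ± 7.04 CPM), the enolase ENO2 (48.1 ± 11.7 to 17.9 ± 1.56 CPM) and NDRG1 (452 ± 42.7 to 225 ± 43.6 CPM). In Lipo against the same WT libraries, camera called the alveolar and the hypoxia list lower. SFTPB and ENO2 (27.7 CPM in Lipo) were lower there too, so falls of these 2 genes against WT were not particular to KO.

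**Figure D1:**
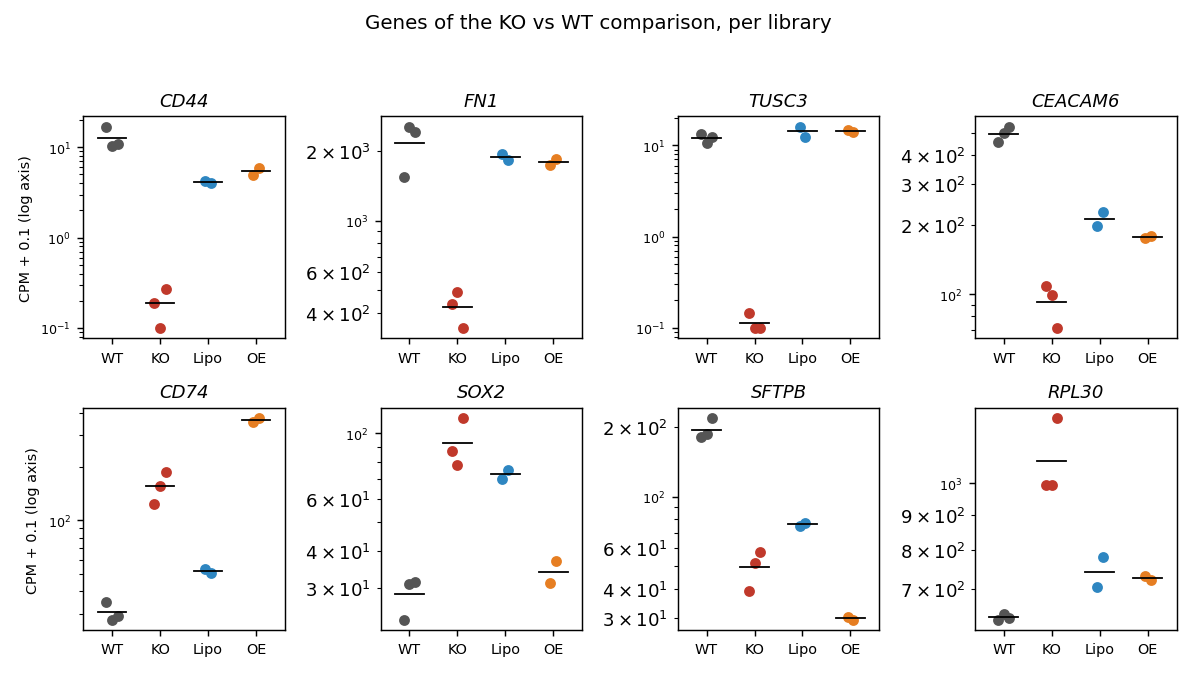
Levels of genes named for KO against WT, as CPM plus 0.1 on a log axis, with a point per library and a line at the mean of each of the 4 groups. CD74 sits above WT in all 3 KO libraries, while FN1 and CEACAM6 sit below it.

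To ask what added TET1 changes, OE was compared with Lipo. Interferon-stimulated genes stood far above the control in both OE libraries. OAS2, an antiviral synthetase, was at 1562 ± 16.0 CPM in OE against 2.15 ± 0.847 in Lipo (720-fold higher, n = 2 each, log2 SE 0.27, adjusted p = 9.20e-12). The antiviral GTPase MX1 was at 791 ± 4.82 against 2.71 ± 0.996 CPM (290-fold), and IFIT3 at 938 ± 12.7 against 5.28 ± 0.769 CPM (177-fold). XAF1, an interferon-induced regulator of cell death, had no reads in Lipo and 113 ± 8.56 CPM in OE (at least 1738-fold higher). The type III interferon IFNL1 had 3162 reads in OE and 1 in Lipo (ratio 3458, 95% interval 620 to 136610). The antiviral RSAD2 reached 264 ± 10.3 CPM, TMEM140 28.7 ± 0.0975 CPM, and the chemokines CXCL10 and CXCL11 48.7 ± 2.87 and 28.0 ± 0.307 CPM, each with 8 reads or fewer in Lipo. The log2 change was 9.79 for RSAD2 and 7.37 for TMEM140 without Lipo 3. Too few Lipo reads for a fold are left without Lipo 2 for either, or without 1 of the Lipo libraries for CXCL10.

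Among the genes named by the rule, which asks for a mean log2 CPM of at least 2, the falls in OE were smaller than the rises. FMO5, a flavin monooxygenase, fell 6.12-fold from 5.11 ± 2.01 to 0.831 ± 0.0601 CPM (adjusted p = 3.73e-04), the lipid flippase ATP8A1 fell 4.02-fold from 17.2 ± 1.59 to 4.27 ± 0.648 CPM, and C16orf89 and the endocytic receptor LRP2 fell by 2.17 and 1.95 on the log2 scale. SLC4A8 fell by 2.07, or 2.71 without OE 1, and the noncoding LINC00342 by 2.11. The fall of the water channel AQP4 (log2 -2.27) did not pass without Lipo 3 (adjusted p = 0.0678) or OE 2 (0.0803). That of the Fc receptor FCGR2A (-2.16) did not pass without OE 1 (0.0857) and was -3.27 without OE 2. That of LONRF2 (-2.04) did not pass without Lipo 2 (0.0907) or OE 1 (0.135). The antisense RNA PCAT6 (-1.92) lost its call without any 1 of Lipo 2 (0.0684), Lipo 3 (0.0727), OE 1 (0.112) and OE 2 (0.0990). In all, 1950 genes passed, 1075 higher and 875 lower in OE, and 936 differed at least 2-fold (581 higher, 355 lower). The count was 769 without Lipo 2, 673 without Lipo 3, 695 without OE 1 and 792 without OE 2. It was 3953 with WT as control and 5664 when OE and Lipo alone were fitted, so it too depended on libraries outside the comparison.

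The interferon list rose almost whole in OE. Of its 46 tested members, 45 rose and none fell (45 also adjusted over the list alone), with a median log2 change of 3.83 and GBP2 (log2 0.19, adjusted p = 0.640) as the exception. IFI44L went from 4.66 ± 0.114 to 723 ± 6.99 CPM (155-fold) and IFIT1 from 4.41 ± 0.825 to 651 ± 2.59 CPM (147-fold). Of 30 Chemokines and cytokines 22 rose (23 adjusted over the list alone), such as the death ligand TNFSF10 (7.87 ± 1.70 to 80.6 ± 3.56 CPM, 10.3-fold). Of 22 NF-kB targets 18 rose, also adjusted over the list alone, such as TNFAIP2 (59.0 ± 1.48 to 536 ± 12.6 CPM) and the NF-kB subunit RELB (10.1 ± 0.675 to 68.3 ± 2.06 CPM). Of 13 genes of Nucleic acid sensing 8 rose (9, with 1 falling, adjusted over the list alone), including SAMHD1, which degrades deoxynucleotides (55.1 ± 1.55 to 308 ± 3.59 CPM), the DNA sensor IFI16 (252 ± 11.9 to 840 ± 5.01 CPM) and the kinase EIF2AK2, activated by double-stranded RNA (152 ± 5.71 to 522 ± 6.26 CPM). These 4 lists were called higher by camera, with adjusted p = 3.17e-07, 5.50e-04, 0.00155 and 0.00155 with an estimated correlation.

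Both lists of antigen presentation were called higher too. In the class I list 10 of 16 members rose (13 adjusted over the list alone). The class I transactivator NLRC5 rose from 11.6 ± 2.95 to 78.5 ± 6.01 CPM and HLA-B from 8.62 ± 0.891 to 169 ± 1.92 CPM, with the caveat that reads can be shared between HLA genes. In the class II list 4 of 6 rose (4, with 1 falling, adjusted over the list alone), with CD74 up 6.97-fold from 52.0 ± 1.78 to 363 ± 13.7 CPM and the protease CTSS from 64.4 ± 1.97 to 159 ± 8.05 CPM. Of 19 Immune checkpoint and NK ligands 8 rose and 1, VTCN1, fell (8 and 2 adjusted over the list alone), and 5 rose without Lipo 2. The number falling was 2 without KO 1, KO 2 or WT 1 and 3 with WT as control. Galectin-9, LGALS9, rose 14.5-fold to 185 ± 13.5 CPM, IDO1 12.9-fold to 87.2 ± 6.68 CPM, and CD274, which encodes PD-L1, 2.36-fold from 45.4 ± 1.22 to 107 ± 0.389 CPM. With WT as control the log2 change of CD274 was 0.56 in place of 1.24, and still passed. The 3 lists were called higher, with adjusted p = 0.00191, 0.0149 and 0.00535 with an estimated correlation, and the class II value was 0.0699 without Lipo 2.

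Lists of matrix proteases and histones were called higher in OE as well. Of 18 Matrix proteases and inhibitors 9 rose (10 adjusted over the list alone), with the collagenase MMP13 up 22.7-fold to a mean of 453 CPM and PLAUR 4.84-fold from 50.1 ± 4.98 to 242 ± 8.94 CPM (adjusted p = 0.00710 for the list with an estimated correlation). That count was 4 without Lipo 2 or Lipo 3 and 5 without OE 1. Of 17 Replication-dependent histones 8 rose (10 adjusted over the list alone), among them H2AC6 (17.5 ± 1.12 to 43.4 ± 0.626 CPM). The histone list was called (adjusted p = 4.46e-05, and adjusted p = 0.0459 with an estimated correlation). The estimated value was 0.0884, 0.105, 0.0687 and 0.0695 without Lipo 2, Lipo 3, OE 1 and OE 2, where 3, 3, 4 and 3 members rose, and it also passed 0.05 without WT 1 (0.0853), WT 3 (0.0732) or KO 2 (0.0868) and with protein-coding genes alone (0.0501).

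Lists of mitotic, mitochondrial and lung lineage genes were called lower in OE, by calls that did not hold with an estimated correlation. Of 30 G2/M genes 12 fell (23 adjusted over the list alone), such as topoisomerase TOP2A (581 ± 22.9 to 328 ± 0.367 CPM) and the spindle protein DLGAP5 (104 ± 4.85 to 58.9 ± 1.11 CPM). The list had adjusted p = 0.0925 with an estimated correlation, and 7, 6, 3 and 5 members fell without Lipo 2, Lipo 3, OE 1 and OE 2, 19 without KO 1 or KO 3, and 20 without WT 1. Of 13 Mitochondrially encoded genes 11 fell, also adjusted over the list alone (adjusted p = 0.128 with an estimated correlation), with MT-ND5 at 2799 ± 96.6 against 6384 ± 719 CPM, and 7 fell without Lipo 2, OE 1 or OE 2. The mitochondrial share of counts was 4.81% in OE and 8.38% in Lipo, and with WT (5.71%) as control 6 fell and 1 rose, while 6 fell with all 5 wild-type-labelled libraries. Of 22 Alveolar type 2 and club cell genes 8 fell and 2 rose (9 and 2 adjusted over the list alone, adjusted p = 0.0822 with an estimated correlation). SFTA3 fell from 63.9 ± 3.14 to 30.4 ± 0.384 CPM and SFTPB from 75.9 ± 1.69 to 29.7 ± 0.586 CPM, and LAMP3, also an interferon-induced lysosomal protein, rose from 3.62 ± 0.109 to 224 ± 1.17 CPM. Their number falling was 4 without Lipo 3 or OE 1 and 5 without OE 2, and 1 rose without any 1 Lipo or OE library.

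A further 6 lists were called in OE with the preset correlation alone. Of 21 YAP and TAZ targets 8 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.226 with an estimated correlation), such as the kinase NUAK2 (12.8 ± 2.01 to 47.9 ± 0.808 CPM), and 3 or 4 rose and none fell without any 1 Lipo or OE library. Against WT 7 rose and 5 fell. Of 24 genes of the Unfolded protein response 7 rose and 2 fell (7 and 3 adjusted over the list alone, adjusted p = 0.134 with an estimated correlation), among them PPP1R15A (280 ± 20.7 to 701 ± 3.98 CPM). Only 2 rose without any 1 Lipo or OE library, and 15 rose with WT as control, with 1 falling in each of these. That call ended without Lipo 2 (0.0686), Lipo 3 (0.0723), OE 1 (0.0574), OE 2 (0.0537) or WT 3 (0.0509). Of 12 Basal and squamous genes 6 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.134 with an estimated correlation), with the keratin KRT17 at 13.6 ± 1.47 CPM in OE (log2 4.50, or 5.31 without Lipo 3). The number rising was 3 without Lipo 2 and 4 with all 5 wild-type-labelled libraries as control, and the number falling 1 with that control or without OE 2. The call was lost without any 1 of the 2 Lipo, 2 OE and 3 KO libraries, with values from 0.0537 without OE 2 to 0.117 without Lipo 3. In the DNA methylation machinery 3 of 26 rose and 3 fell (3 and 5 adjusted over the list alone, adjusted p = 0.128 with an estimated correlation). TET1 is itself a member, and the mean log2 change (0.571) and the median (-0.0556) differed in sign. The number falling was 1, 0, 1 and 0 without Lipo 2, Lipo 3, OE 1 and OE 2, and 5 without WT 1 or with WT as control. GADD45B and GADD45A, stress-induced genes, rose by 1.57 and 1.27. The call ended without Lipo 2 (0.0838), Lipo 3 (0.0793), OE 2 (0.0594) or WT 1 (0.0515). Of 31 DNA repair genes 2 fell, the kinases ATM (34.4 ± 1.09 to 16.6 ± 1.67 CPM) and PRKDC (455 ± 20.8 to 270 ± 0.0254 CPM), also adjusted over the list alone (adjusted p = 0.386 with an estimated correlation), and the call ended without Lipo 2 (0.0513) or OE 1 (0.0502). Without KO 3 the number falling was 4, with all 5 wild-type-labelled libraries as control 5, and with WT as control 9. Of 38 Cytosolic ribosomal proteins 3 fell, also adjusted over the list alone (adjusted p = 0.557 with an estimated correlation), none without any 1 Lipo or OE library, 5 without KO 2 or WT 1, 6 without KO 1 and 8 without KO 3. It was 5 with library size alone and 7 with DESeq2 or no filter. Against WT as control the calls of the YAP and TAZ (0.109), basal (0.197), DNA methylation (0.0761) and ribosomal (0.532) lists ended, and with protein-coding genes alone those of the unfolded protein, basal and DNA methylation lists (each 0.0881).

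**Figure D2:**
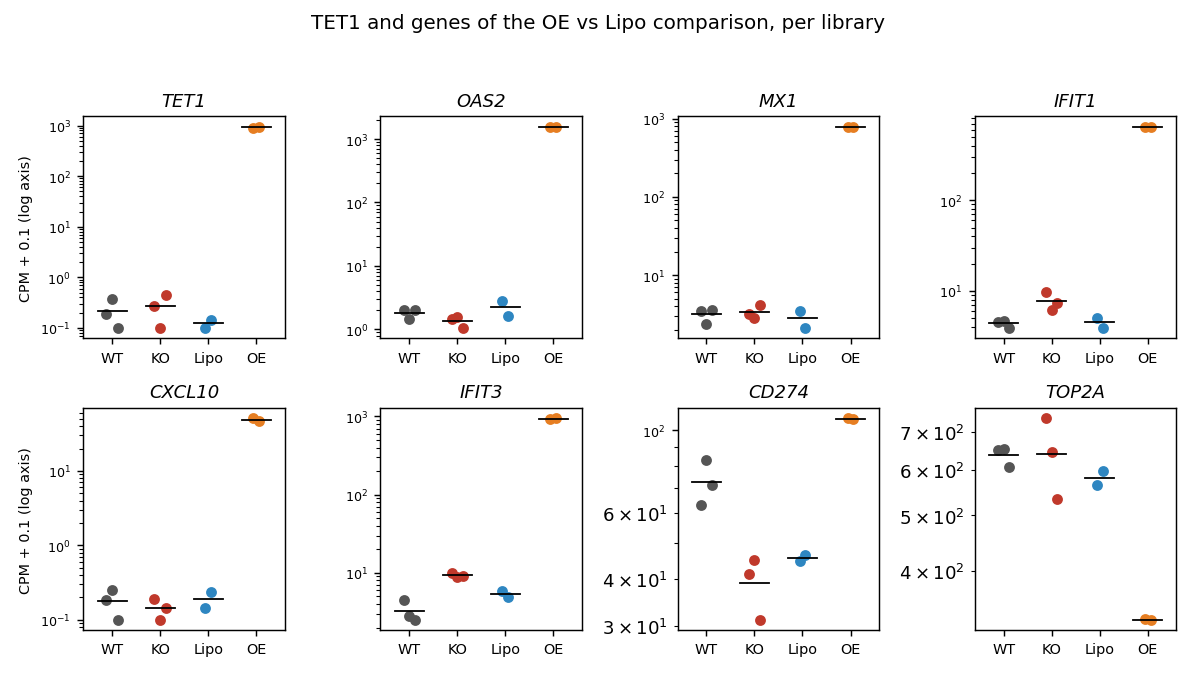
Levels of genes named for OE against Lipo, as CPM plus 0.1 on a log axis, with a point per library and a line at the mean of each of the 4 groups. OAS2, MX1 and IFIT3 sit above every other library in both OE libraries.

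Both kinds of wild-type library were compared to measure the background between them. GDF15, a secreted stress-responsive cytokine, was 7.27-fold higher in Lipo than in WT (83.3 ± 3.90, n = 2, against 11.4 ± 4.42 CPM, n = 3, adjusted p = 6.31e-04). FRAS1 was 3.96-fold higher and the hexokinase HKDC1 3.13-fold higher (15.9 ± 0.428 against 5.07 ± 0.304 CPM). The receptor kinase ROS1 was 5.18-fold lower (2.74 ± 0.132 against 14.2 ± 3.87 CPM), and the nuclear noncoding RNA MALAT1 6.06-fold lower (196 ± 38.2 against 1189 ± 584 CPM). MALAT1 was as low in OE 1 and OE 2 (206 and 202 CPM), while the KO libraries ranged from 677 to 2057 CPM. Its low level was therefore shared by Lipo and OE, and a comparison of OE with WT holds it too. GOLGA8A fell by 2.81, or 3.77 without Lipo 2, and CDK5RAP3 by 2.34, or 3.02 without Lipo 2, with adjusted p = 0.0506 without Lipo 3. The calls of HES1 (log2 1.75), OASL (1.64), MALAT1 and MMP9 (-2.38) all ended without Lipo 2 (adjusted p = 0.0806, 0.109, 0.226 and 0.288) and without Lipo 3 (0.127, 0.192, 0.348 and 0.372). Those of MALAT1 and MMP9 also ended without OE 2 (0.0660 and 0.0575), and that of MALAT1 without OE 1 (0.0658), WT 1 (0.0675) or WT 3 (0.0804). MMP9 was at -1.69 without WT 1. A total of 586 genes passed, 209 higher and 377 lower in Lipo. The count was 82 without Lipo 2, 34 without Lipo 3, 318 without WT 2, 352 without WT 3, 966 without KO 1 and 977 without KO 3. It was 1100 with no filter and 992 with DESeq2.

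Lists of stress and mitochondrial genes were called higher in Lipo. Of 24 genes of the Unfolded protein response 7 rose and none fell (12 adjusted over the list alone), led by the pseudokinase TRIB3 (2.76-fold, log2 SE 0.18), and 2, 1 and 11 rose without Lipo 2, Lipo 3 and KO 3. Adjusted p for the list was 0.0164 with an estimated correlation, and 0.0587, 0.0589, 0.0641 and 0.0565 without Lipo 2, WT 3, KO 1 and KO 3. Of 13 Mitochondrially encoded genes 9 rose and 1, MT-ND6 (log2 -1.80), fell (12 and 1 adjusted over the list alone, adjusted p = 0.195 with an estimated correlation), beside the mitochondrial share of 8.38% in Lipo and 5.71% in WT. Only 1 rose without Lipo 2, none without Lipo 3, and 4 without OE 1, OE 2 or WT 2. Of 23 p53 targets 3 rose, also adjusted over the list alone (adjusted p = 0.0923 with an estimated correlation), GDF15 alone without Lipo 2 or Lipo 3. Of 46 Interferon-stimulated genes 4 rose and 1 fell (12 and 4 adjusted over the list alone, adjusted p = 0.0923 with an estimated correlation). Without Lipo 2 or Lipo 3 no interferon-stimulated gene passed, and the list's call ended without Lipo 2 (0.0540). The number rising was 9 and 7 without KO 1 and KO 3, and 2 without OE 1, OE 2, WT 2 or WT 3.

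Of 22 Mesenchymal and EMT genes 6 fell in Lipo (8 adjusted over the list alone, adjusted p = 0.0279 with an estimated correlation), none without Lipo 2 or Lipo 3, and 3 without OE 2 or WT 2. The estimated value was from 0.0520 to 0.0964 without WT 2, WT 3, KO 1, KO 3, Lipo 2 or Lipo 3. Of 22 Alveolar type 2 and club cell genes 6 fell and 2 rose (7 and 4 adjusted over the list alone, adjusted p = 0.156 with an estimated correlation), including surfactant proteins SFTPA2 (1645 against 4209 CPM) and SFTPB (75.9 against 195 CPM), and the call ended without Lipo 2 (0.0613, 3 falling) or Lipo 3 (0.111, 2 falling). The other 9 lists called with the preset correlation had adjusted p from 0.0801 to 0.605 with an estimated correlation. Those called higher were Cholesterol biosynthesis (3 of 23 rose, 4 adjusted over the list alone), MAPK pathway output (5 of 22, 7), class II (2 of 6, 3), NRF2 targets (3 of 22, 8 with 1 falling), Fatty acid synthesis and lipid storage (2 of 23, 4), Oxidative phosphorylation subunits (0 of 34, 0), Cytosolic ribosomal proteins (0 of 38, 0) and class I genes (0 of 16, 0). Without KO 1, KO 2 and KO 3 the number rising was 2, 1 and 6 for oxidative phosphorylation, and it was 1 and 2 for ribosomal proteins without KO 1 and KO 3. Hypoxia and glycolysis was called lower (8 of 32 fell and 1 rose, also adjusted over the list alone). Of these calls, class I ended without Lipo 2 (0.104) or WT 3 (0.0608) and with protein-coding genes alone (0.0548), fatty acid synthesis without WT 1 (0.0512), and hypoxia without Lipo 3 (0.0505) or WT 2 (0.0771). No member of the cholesterol, MAPK, class II, NRF2, fatty acid and hypoxia lists passed without Lipo 2 or Lipo 3. The number falling was 4 without WT 2 for hypoxia. The number rising was 3 without OE 1, OE 2, WT 2 or WT 3 for MAPK, 1 without WT 2 or WT 3 for class II, and 6 without KO 1 or KO 3 for NRF2. For fatty acid synthesis it was 5 without KO 1 and 1 without WT 2 or WT 3. With no filter 13 interferon-stimulated, 6 cholesterol, 5 NRF2 and 4 fatty acid genes rose, and with DESeq2 7 interferon-stimulated, 7 NRF2, 4 fatty acid and 11 unfolded protein genes.

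**Figure D3:**
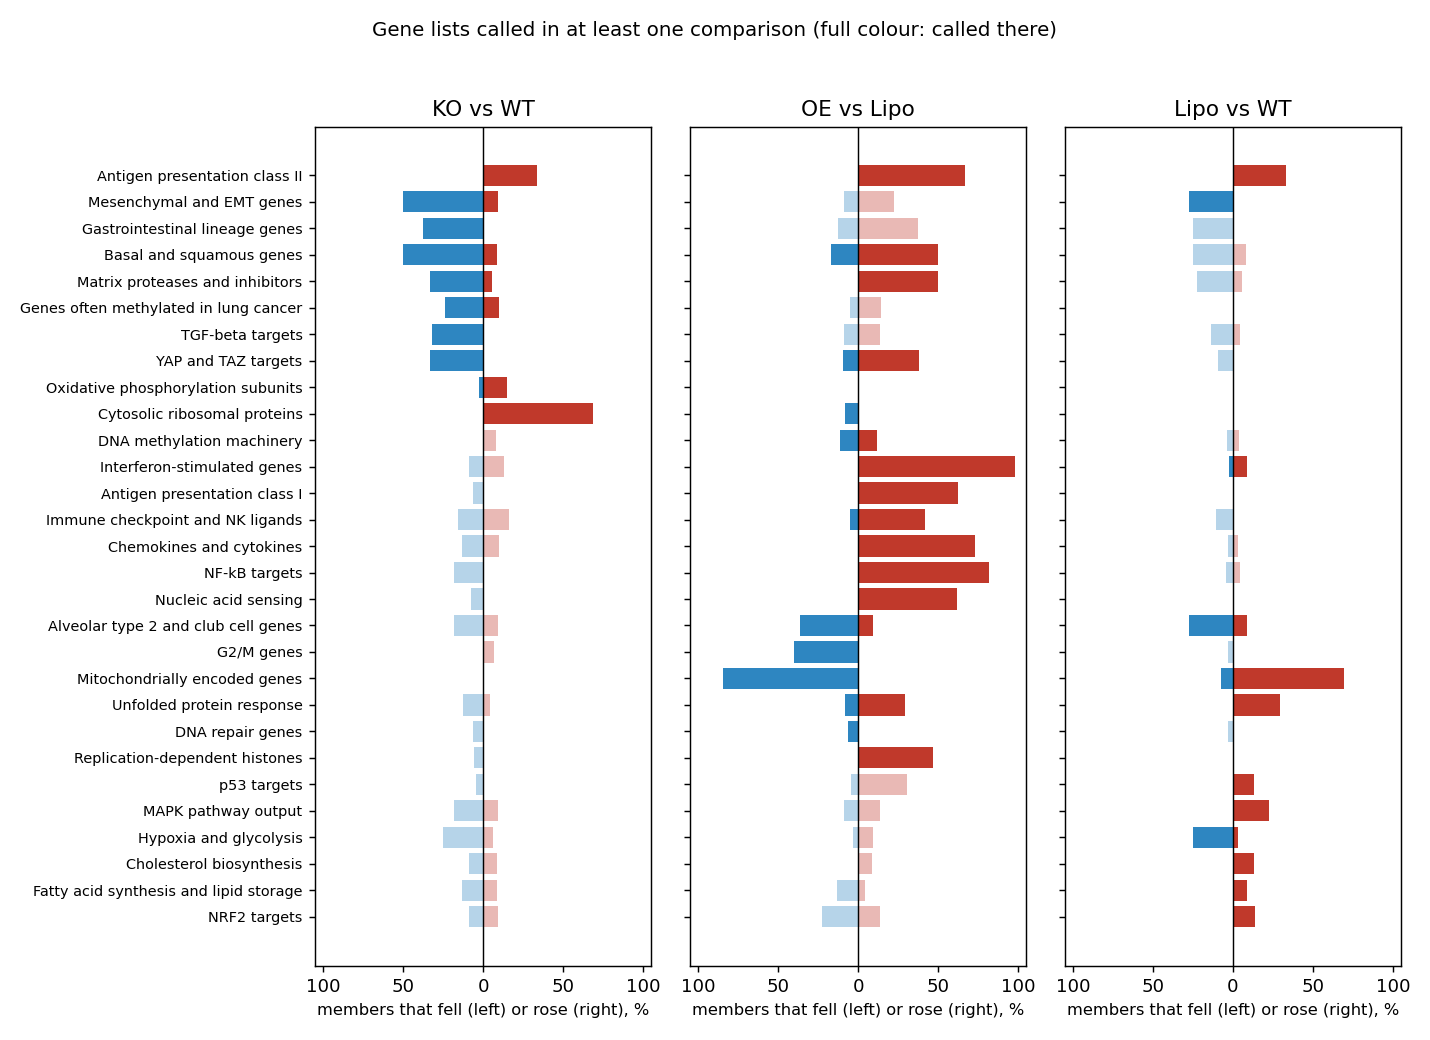
Percent of tested members of each gene list that fell (left) or rose (right) in KO against WT, OE against Lipo and Lipo against WT, for the 29 lists called in at least 1 comparison, in full colour where called. The interferon list reaches 45 of 46 members rising in OE, against 6 in KO and 4 in Lipo.

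Another 3 lists had too few tested members for a list test. Of the 2 Fibroblast marker genes tested, collagen COL1A1 fell in KO from 231 ± 65.2 to 63.9 ± 6.22 CPM (adjusted p = 5.93e-06) and rose in OE from 155 ± 6.87 to 308 ± 7.88 CPM (0.00643). That rise did not pass without Lipo 2 (0.0529), Lipo 3 (0.0817) or OE 2 (0.0519), with WT as control (log2 0.41, 0.125) or with all 5 wild-type-labelled libraries (0.0689). Lumican, LUM, fell in KO by 0.72 (0.0243), though not without WT 1 (0.0666), KO 2 (0.0996) or KO 3 (0.0878) or with WT and KO fitted alone (0.0749). It rose in OE by 0.87 (0.0235), though not without Lipo 2 (0.0847), Lipo 3 (0.218), OE 1 (0.159) or OE 2 (0.0983). Of the 3 Neuroendocrine genes ENO2 alone changed, in KO as given above and in Lipo by -0.80 (0.0316), which did not pass without any 1 of the Lipo and OE libraries, WT 2 or WT 3 (0.0535 to 0.325), and none of the 3 HOX genes changed in any comparison.

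To ask whether the labelled knockout and the addition of TET1 moved genes in opposite ways, the KO and OE effects were compared. PLAUR fell by 0.93 in KO and rose by 2.27 in OE (adjusted p of the difference 1.25e-07). CD274 fell by 0.89 and rose by 1.24 (1.95e-05), PLAU fell by 1.25 and rose by 0.95 (2.80e-06), and TFPI2 fell by 0.99 and rose by 1.08 (4.07e-06). OAS1 fell by 0.88 and rose by 4.64 (2.07e-09), and SLC6A14 fell by 6.82 and rose by 1.86 (4.67e-09). With WT as control, however, the rise of SLC6A14 in OE was 0.51 and did not pass (adjusted p = 0.105), and that of CD274 was 0.56. PLEKHS1 (1.67 and -1.34) and ATP8A1 (0.79 and -2.01) rose in KO and fell in OE. SOX2 did so as well (1.69 and -1.10), but its OE change was 0.25 with WT as control. CD74 rose in both (2.35 and 2.80, adjusted p of the difference 0.202), as did IDO1 (1.57 and 3.69) and IFIT3 (1.55 and 7.47), while SFTPB fell in both (-1.97 and -1.35). With WT as control the OE changes of CD74, IDO1, IFIT3 and SFTPB were 3.57, 4.32, 8.21 and -2.71.

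Of the 430 genes that passed in both comparisons, 296 moved in opposite directions (68.8%) and 134 in the same. With WT as the control of both comparisons, 344 were opposite (1.39 times the number under independence) and 305 in the same direction (1.22 times), against 2.37 and 1.11 times here. Genes lower in KO and higher in OE numbered 173 where 80.1 would be met if the calls were independent (Fisher's exact test, two-sided, adjusted p = 6.13e-23), and genes higher in KO and lower in OE 123 against 44.9 (8.17e-25). Genes lower in both numbered 88 against 65.2 (0.00470) and genes higher in both 46 against 55.1 (0.223). Genes are not independent, so these p-values are too small. Over all 15832 genes the log2 changes were only weakly related (across genes, Pearson's r -0.066, Spearman's correlation -0.115), and the 2 comparisons share no library. The difference itself passed for 2632 genes, 1133 with the higher change in KO and 1499 with the higher change in OE. It passed for 1446, 1373, 1426 and 1532 genes without Lipo 2, Lipo 3, OE 1 and OE 2. The opposite calls numbered 137, 122, 124 and 135 without the same libraries and 179 without WT 2.

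**Figure D4:**
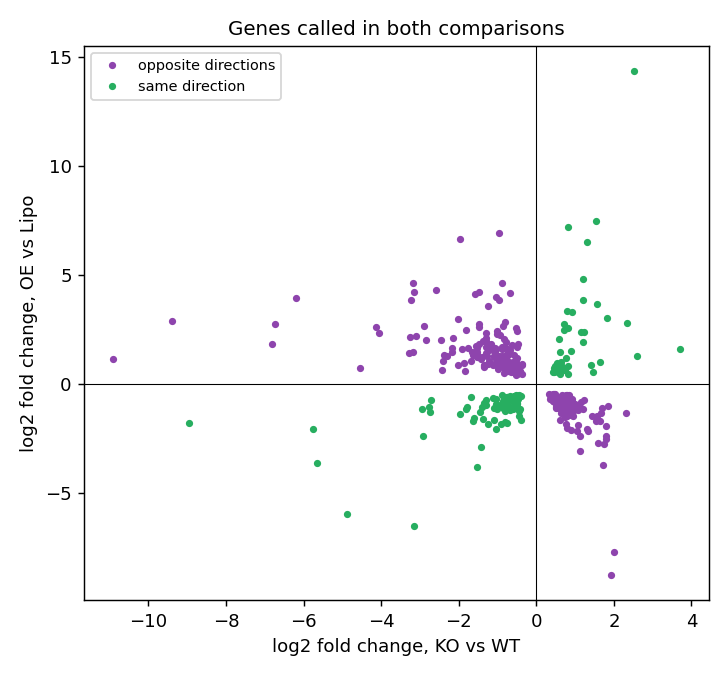
Log2 fold change in KO against WT (horizontal) and in OE against Lipo (vertical) for the 430 genes that passed in both, a point per gene, purple for opposite and green for the same direction. More points, 296 of them, lie in the quadrants of opposite direction.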

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

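The tests without WT 1 and KO 1 together, and those with a replicate block over all 10 libraries, were chosen only after the results had been seen. The splits of the samples and every other alternative had been planned, but what the splits should show was written after. The gene counts stayed within 1.5 times under RLE scaling, library size alone, the stricter filter and protein-coding genes alone in all 4 comparisons, and no scaling moved the median of all genes by more than 0.1. RLE kept 99.1% of the KO calls, 99.5% of the OE calls and 95.6% of the Lipo calls, and DESeq2 kept 99.3% of the KO and 98.7% of the OE calls. Named genes kept direction and call in 2912 of 3182 recomputed values for KO, 3572 of 3960 for OE and 1313 of 1535 for Lipo, and lost the call in 270, 369 and 222. Where a left-out library leaves 1 sample in a group, that sample is assumed to vary like the other groups. For every change in this part the cause was not tested. Depth limits TET1 in WT, KO and Lipo and the folds of genes with few reads in a group.

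With each library left out in turn, the KO count of 1992 ranged from 1125 to 2297, the OE count of 1950 from 673 to 2657, the Lipo count of 586 from 34 to 977, and the count of differing KO and OE effects, 2632, from 1373 to 3023. The genes called in opposite directions, 296, ranged from 122 to 371, and the TET1 change in KO from -0.5536 to 1.83. When the groups compared were fitted alone, the counts were 1216 for KO and 5664 for OE. For the KO and OE effects that fit is the one with all libraries. With the replicate number as a block (replicate block), they were 3368 for KO and 3695 for Lipo. For OE and Lipo taken alone no such fit can be made, as they share only number 2, but over all 10 libraries, where WT and KO link the numbers, the block gave 2678 genes and 3402 differing effects. With a block 8 lists were called in KO, without the gastrointestinal and the often methylated genes, and 15 in OE, where the alveolar, basal, ribosomal and DNA methylation lists lost the call and the mesenchymal list was called. With an estimated correlation the mesenchymal list in KO (adjusted p = 0.681) and the histones in OE (0.0624) did not pass with it. Whether the numbers pair the libraries was not settled, and the main fit took no account of any pairing. WT and KO deviations correlated by 0.328, 0.0577 and 0.185 at numbers 1 to 3, and by -0.238 to 0.0920 at unlike numbers. WT 2 correlated best with KO 3 (0.0920). With WT as control the OE count was 3953, or 4510 with the block. No filter gave 1100 genes for Lipo, and DESeq2 gave 992. Without WT 1 and KO 1 the counts were 3477 for OE, 1157 for Lipo and 569 for opposite directions. Of the 10 lists called in KO, 18 in OE and 15 in Lipo, 1, 9 and 2 passed with an estimated correlation, and fry called 18 in KO and 28 in OE.

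Of the 173 genes named for OE, 9 reversed with WT as control, and also with the block added. They are SOX2 (0.2489 and 0.3241), TGFB2 (-0.0802 and -0.2312), PFKFB3 (-0.1904 and -0.2747), KDM3A (-0.1439 and -0.227), SCD (0.1438 and 0.2019), FRAS1 (0.9656 and 0.9732), IDH1 (0.1459 and 0.1042), CAV1 (-0.4933 and -0.5856) and MT-CO2 (0.0555 and 0.0878). CAV1 was also at -0.1564 with all 5 wild-type-labelled libraries.

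In the other splits of the WT and KO libraries, 1 of the 10 splits, the real one, gave as many genes (1216 with these 6 libraries, against at most 1 in another) and 1 as many called lists (10, against at most 8). The 10 splits are too few for a share under 0.05, the smallest being 0.1.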

Other observations

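The tests of explanations in this part were all chosen after the results had been seen, as were the limits that define a gene near 0. Growth factor and lipid genes changed in KO without their lists being called by camera, though fry called the MAPK (adjusted p = 0.0343) and EGFR ligand lists (0.0233) lower. The phosphatases DUSP5 (74.3 ± 8.53 to 20.2 ± 4.94 CPM) and DUSP6 (650 ± 48.8 to 318 ± 69.7 CPM), which switch off ERK signalling, fell, and SPRY1 (log2 1.04) and MYC (237 ± 35.7 to 408 ± 94.8 CPM) rose, in a MAPK pathway output list with 4 of 22 members lower and 2 higher (5 and 2 adjusted over the list alone, adjusted p = 0.141). Of 6 EGFR family ligands 3 fell, also adjusted over the list alone (adjusted p = 0.143), among them amphiregulin, AREG (344 ± 52.1 to 228 ± 15.6 CPM). The secreted Wnt antagonist DKK1 fell from 22.0 ± 1.16 to 6.27 ± 1.02 CPM and WNT5A by 1.62 on the log2 scale (in a list with 2 of 10 lower and 1 higher, 3 and 3 adjusted over the list alone, adjusted p = 0.731, its median 0.16 and its mean -0.02). In lipid metabolism LPIN2 fell from 92.8 ± 19.6 to 29.1 ± 1.87 CPM and PLIN2 from 32.2 ± 0.928 to 17.4 ± 2.47 CPM, while SQLE, an enzyme of cholesterol synthesis, rose from 51.6 ± 3.22 to 91.4 ± 10.1 CPM. Their lists had adjusted p = 0.307 (fatty acid synthesis, 3 of 23 lower and 2 higher, 5 and 2 adjusted over the list alone) and 0.873 (cholesterol, 2 of 23 lower and 2 higher, 3 and 2). The paternally expressed PEG10 rose from 658 ± 92.1 to 999 ± 121 CPM, and the DNA repair kinase PRKDC fell from 445 ± 8.05 to 264 ± 33.1 CPM.

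In OE, DKK1 went the other way, from 7.03 ± 0.112 to 39.1 ± 1.45 CPM (log2 2.47, or 0.83 with WT as control), and the KO and OE effects differed (adjusted p = 3.01e-08). It was also lower in Lipo than in WT (log2 -1.65). Of 23 p53 targets 7 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.0836), among them the death genes PMAIP1 (134 ± 8.42 to 297 ± 15.0 CPM) and FAS (22.2 ± 1.61 to 45.4 ± 5.56 CPM). The chaperone DNAJA1 rose from 283 ± 2.46 to 566 ± 10.4 CPM in a heat shock list with 3 of 12 higher, also adjusted over the list alone (adjusted p = 0.139). The tight junction gene CLDN1 (32.4 ± 5.00 to 114 ± 1.46 CPM), the fibronectin receptor ITGA5 (41.9 ± 2.27 to 128 ± 13.9 CPM) and the secretory cell gene AGR2 (154 ± 9.73 to 330 ± 15.8 CPM) rose, and the immediate early gene FOS fell (260 ± 1.17 to 97.1 ± 6.02 CPM), while camera did not call their lists (adjusted p = 0.647 for epithelial, 0.0583 for mesenchymal, 0.224 for gastrointestinal and 0.935 for MAPK genes). RASSF1, often methylated in lung cancer, rose from 8.72 ± 0.211 to 23.4 ± 0.109 CPM, in a list with 3 of 21 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.686). Of the lists in this paragraph fry called the p53, heat shock, mesenchymal, gastrointestinal and often methylated ones higher (adjusted p from 0.00214 to 0.0437).

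Of 46 interferon-stimulated genes, 45 were higher in OE than in Lipo. With WT as control 45 members were again called higher, and over the other scalings the fewest were 45, which argues against a property of the Lipo libraries and against normalization as the whole cause. Introduced DNA that is sensed whatever gene it carries stays open. In Lipo against WT 4 members were higher, but the labels do not say that Lipo cells received DNA, and no library is labelled as DNA without TET1. The added TET1 may therefore have raised these genes, or the plasmid may have, and the 2 cannot be told apart here.

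In KO, 42 genes of at least 1 CPM in WT, of 12633 at that level, were at least 32-fold lower, on 16 chromosomes, and 1 gene had gained as much. By the same rule 68 genes had gained and 2 had lost in OE. RAB31, a small GTPase (48.2 CPM in WT, 1.33 in KO), and the neighbours CHDH and IL17RB were among them and are named after their values were seen. Of the 42, 6 had a nearest expressed neighbour that was also near 0, above the average of random draws (0.31, and 6 at most). They were PSG1 with PSG6, SHC3 with a transcript lying within it, and CHDH with IL17RB, also named after their values were seen. So few argue against loss of chromosome segments holding several expressed genes as the whole cause. Loss of a stretch with a single expressed gene would not show in this test. Only 1 of the 42 was near 0 in Lipo or OE, so a loss this deep was rare there. Genes that come and go between cultures of the line stay open, since the 42 were chosen by their KO values. Of them, 4 were lower and 3 higher in OE against Lipo, and 3 lower and 2 higher in Lipo against WT. A difference of the founder cell, fixed when the edited cells were grown, stays open as a candidate explanation beside the loss of TET1, since the labels name no clones. The 14 genes with no reads in any KO library do not decide between these explanations, which cannot be told apart here.

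Opposite calls in KO and OE exceeded those met under independence more than calls in the same direction did, by a ratio of 2.13, where genes that vary easily and are called in both comparisons would give a ratio near 1. With Lipo as the control of OE this argues against such genes as the whole cause. With WT as the control of both comparisons the excesses lay close, at 1.39 times for opposite and 1.22 times for same-direction calls, so the argument does not carry over. Without the members of 7 immune lists (152 genes) 280 opposite calls remained against 116 under independence, a ratio of 2.42. This argues against the members of these lists carrying the overlap. Any immune gene outside the lists stayed in, so a part played by immune genes as a whole stays open. TET1 acting in both directions may account for part of the overlap, although the KO cells did not differ detectably from WT in TET1 RNA. With 1 control for both comparisons, opposite calls numbered 341 against 177 under independence for all 5 wild-type-labelled libraries, but 344 against 248 (a ratio of 1.39, with 305 against 249 in the same direction) for WT. A difference between the Lipo and WT controls stays open as a source of part of the excess, since the 2 controls give unlike ratios. A shared control by itself also moves the covariance of the changes upward (0.0587 for WT and 0.0418 for all 5 in 10 draws without effects, against 0.0240 and -0.0512 here). No gene was called in both comparisons in any draw, but as the draws held no effects to call, this says nothing about the overlap.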
